A study of Mus musculus with 7 samples.

How the data were processed

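Libraries (Smart-Seq v4, a low-input kit) had been made from RNA of sorted splenic plasma cells and sequenced on HiSeq X instruments, per the labels' protocols. The deposited table holds expected counts, that is estimated counts per gene that need not be whole, for 45706 genes in 7 libraries. Between 27.2% and 30.2% of the nonzero values in a library were not whole. The submitters' processing notes name STAR 2.6.1, Salmon 1.4.0 and the GRCm38 genome build; which of these tools made the counts, and with which annotation, is not given in the sources used here. Totals of the deposited expected counts differed between libraries, from 24821559 to 34516200, so they had not been scaled to a common depth. These totals do not show whether the counts had been adjusted in another way. All 7 columns were matched to samples by name. Groups came from the genotype labels, with 3 samples labelled Slc2a1-deleted and 4 Cre controls, and replicate numbers came from the titles.

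The expected counts were rounded to whole numbers. Genes were filtered with filterByExpr by group, which left 11006, scaled with TMM factors and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, robust) on genotype alone, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors of log2 fold changes were derived from the fold change and the F statistic. CPM values are TMM-scaled, computed from the deposited counts. The common dispersion was 0.69. Lists of genes (33, fixed before the data were examined) were tested with camera from limma 3.58.1 at a preset correlation of 0.01 where at least 5 members were tested, which held for 30 lists without the sex-linked one, and again with an estimated correlation and with fry. Shares of immunoglobulin and mitochondrial counts were compared by two-sided exact permutation tests over 35 assignments, adjusted over 12 measures. Intervals for pooled ratios are exact Poisson intervals of the control count, and they and the floor of 3 counts cover counting error only.

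Genes were named by a rule fixed before the data were examined: every tested hexose transporter; up to 15 genes per direction with the largest fold change among those past the threshold, with a mean log2 CPM above 2 and no overlap between groups, without immunoglobulin V, D and J segments and number-only models; and up to 4 members of each list with the smallest p. The rule took 153 genes, and 119 are discussed. This selection departs from the rule: it was made after the values and their stability under other settings had been seen, and the 34 genes left out were less stable as a group. A few of these are not reported here for reasons unrelated to their values. Gene positions, biotypes and lengths came from GENCODE M21, on the same build, in which 45143 of the 45706 gene IDs were found. A coding length was available for 91.3% of tested genes.

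Alternatives planned before the data were examined were DESeq2 1.42.0, limma-voom without and with quality weights, RLE and upper-quartile factors, removal of immunoglobulin genes, no and a stricter low-count filter, the replicate number as a block, a non-robust fit, a test against a fold change of 1.2, and leaving out each library. A sex covariate was planned only for the case of both sexes, and was not run because Xist had no count in any library. Length corrections were added after the data were seen. Spearman's rho between log2 fold change and 10 length measures had been compared first, and coding length was taken because its rho, 0.59, was the highest; the others ran from -0.01 to 0.47. In all, 5 corrections were run, each subtracting loess trends (span 0.3) per library as offsets: on coding length; on coding length, untranslated length and GC content; on transcript length; on transcript length and then GC content; and on both iterated for 3 rounds. The first 2 used 9819 protein-coding genes without immunoglobulin genes. The second is the one whose values are called corrected in the text. It was settled on after the data were seen, and of the 5 it gave the most lists called and the smallest adjusted p for Slc2a1.

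The code was tested on simulated counts for this comparison, drawn from the real means, library sizes and dispersions with 200 changed genes. In a simulation of 10401 tested genes with no length trend, edgeR recovered 0% of 2-fold, 22.7% of 4-fold and 65.2% of 16-fold changes and called 0 unchanged genes, while estimated log2 fold changes had medians of 1.05, 1.95 and 4.02 for true values of 1, 2 and 4. DESeq2 called 72 unchanged genes in the same counts. With a length trend imposed on 1 group, edgeR called 920 unchanged genes among 10468, and 0 among 9402 after either coding length correction. The imposed trend followed coding length exactly, the measure that these corrections remove. It therefore does not show how well they work on the real libraries. Camera called 0 lists when none was changed and 1 when 1 was doubled. The simulated genes were drawn independently, so this does not test camera where genes vary together.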

Results

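The data are RNA sequencing counts from 7 samples of mouse splenic plasma cells, the antibody-secreting cells of the B lineage, sorted by flow cytometry for surface CD138 and TACI. All mice carried a Cre recombinase driven by the CD23 gene, which is active in mature B cells. In 3 samples the labels also give floxed alleles of Slc2a1, the gene of the glucose transporter GLUT1, and these are called here the deleted-labelled libraries. The other 4 samples carried Cre without floxed alleles and are called the controls. Total counts ran from 25224454 to 26964486 in the deleted-labelled libraries and from 24821559 to 34516200 in the controls. The single comparison asks how plasma cell transcripts differ with this genotype label, which is meant to remove GLUT1 from B cells. Loss of GLUT1 or of glucose import was not measured in these data. The series title places the comparison in the balance of anaplerosis, the refilling of mitochondrial carbon intermediates. The labels do not say whether each sample came from its own mouse, so p-values measure the spread between these samples, which may be partly technical.

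Slc2a1 itself (ENSMUSG00000028645, GRCm38 chromosome 4, 119108711 to 119137983, plus strand) was not lower in the deleted-labelled libraries. Its level was 27.2, 19.7 and 34.3 CPM in deleted-labelled replicates 1, 2 and 3, against 21.6, 14.3, 8.59 and 18.6 CPM in control replicates 1 to 4. The means were 27.1 ± 7.29 (SD, n = 3) and 15.8 ± 5.64 CPM (SD, n = 4), a log2 fold change of 0.78 with a standard error of 0.38 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.155). The counts cover the whole gene, so exons outside the floxed part are included and could carry reads from a deleted allele. As fitted, whole-gene counts showed neither a decrease of the targeted gene nor a rise past the threshold. Every direction below is between libraries as labelled. Of the other hexose transporters, Slc2a3 (6.33 ± 2.38 against 1.32 ± 2.57 CPM), Slc2a6 (15.6 ± 6.41 against 4.40 ± 3.49 CPM), Slc2a8 (10.1 ± 4.20 against 8.49 ± 4.36 CPM) and Slc45a4 (4.68 ± 1.29 against 1.39 ± 1.88 CPM) did not pass the test either (SD, n = 3 against 4). The direction of Slc2a1 turned in all 5 corrections for gene length that were tried after the data were seen, with log2 fold changes from -1.62 to -0.94 and edgeR adjusted p from 0.0227 to 0.127. The median of all genes also fell below 0 in these corrections. Relative to it Slc2a1 was at log2 -1.31 to -0.65.

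**Figure D1:**
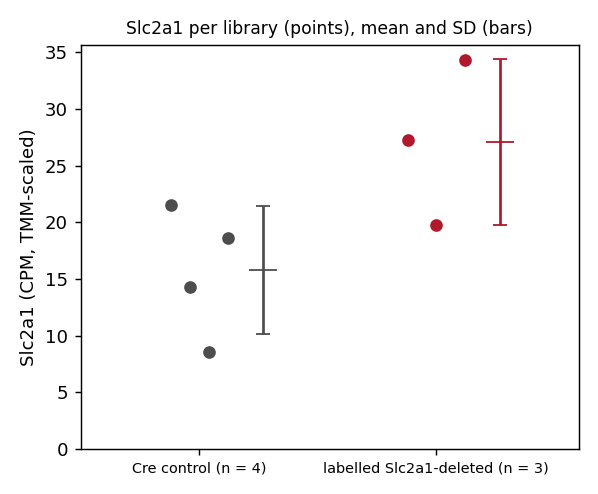
Slc2a1 in CPM (TMM-scaled) for each library, with each group's mean and SD. The deleted-labelled libraries sit between 19.7 and 34.3 CPM and the controls between 8.59 and 21.6 CPM.

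Across the transcriptome, 1825 genes were higher and 1595 lower in the deleted-labelled libraries among 11006 tested (edgeR, adjusted p threshold 0.05). With upper-quartile factors in place of TMM the split was 1319 higher and 2015 lower, and the median log2 fold change of all tested genes moved from 0.62 to 0.23. Leaving out deleted-labelled replicate 1, 2 or 3 left 1052, 941 or 1033 genes higher. The calls separated by the length of the coding sequence. Of 1072 protein-coding genes with coding sequences under 500 bases, 21 were higher and 625 lower, with a median log2 fold change of -1.64. Of 1390 genes with 2000 to 3000 coding bases, 429 were higher and 13 lower, with a median of 2.28. Spearman's rho between fold change and coding length was 0.59 across 9819 genes, which are not independent replicates. The slope of log2 CPM on coding length was 0.63 ± 0.11 per doubling in the deleted-labelled libraries (SD, n = 3) and -0.48 ± 0.11 in the controls (SD, n = 4; exact permutation p = 0.0286, two-sided, the smallest that 35 assignments allow; 0.0429 after adjustment over 9 library measures). The controls also held more 7SL RNA, the RNA of the signal recognition particle, at 2.08 ± 0.52% of counts against 0.244 ± 0.020% (SD, n = 4 and 3; exact p = 0.0286, adjusted 0.0429). Fewer genes reached 10 counts in the controls, 9192 ± 704 against 10921 ± 359 (SD, n = 4 and 3; exact p = 0.0286, adjusted 0.0429). Each of these tests gave the smallest possible p, so its adjusted value depends on how many of the 9 measures reach it. Among the 9, the median deviations of genes with short and with long coding sequences restate the length slope. The slope, 7SL share and number of genes lined up with the labels in all 7 libraries, so genotype and library composition cannot be separated by the design. Values with offsets for coding length, untranslated length and GC content, 1 of 5 corrections that were all chosen after the data were seen, therefore stand beside the gene groups below and are called corrected values. With it, 496 genes were higher and 1288 lower among 9819, with an all-gene median of -0.31.

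**Figure D2:**
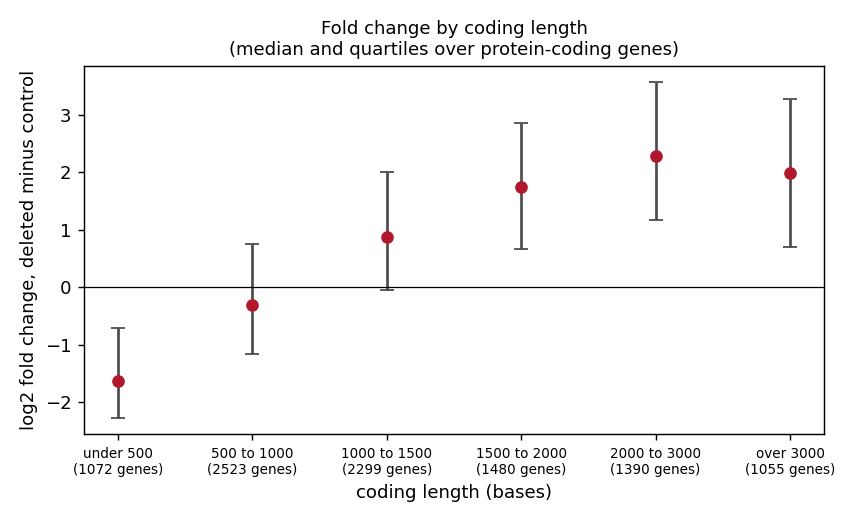
Log2 fold change (deleted-labelled minus control) of tested protein-coding genes in 6 bins of coding length in bases. Points are medians and bars run from the lower to the upper quartile, and the median goes from -1.64 in the shortest bin to 2.28 at 2000 to 3000 bases.

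Genes of the amino acid response driven by the transcription factor ATF4 were higher in the deleted-labelled libraries. Of 35 tested members 22 rose and 1 fell (23 and 1 adjusted over the list alone), with a median log2 fold change of 2.50, which is 1.88 above the all-gene median. Nars, an asparaginyl-tRNA synthetase (chromosome 18, 64499647 to 64516652), rose from 17.01 ± 1.82 to 197 ± 6.56 CPM (SD, n = 4 and 3). Asns, asparagine synthetase, rose from 43.4 ± 7.56 to 242 ± 26.7 CPM, Slc3a2, a subunit of amino acid transporters, from 446 ± 121 to 2520 ± 178 CPM, and Gars, a glycyl-tRNA synthetase, from 9.84 ± 3.97 to 114 ± 23.2 CPM. The list passed camera with a preset correlation (adjusted p = 1.25e-07) and did not with an estimated one (adjusted p = 0.10). The median coding length of the list was 1506 bases. Its corrected median was 0.92, with 10 members higher and 3 lower, and Nars, Asns, Slc3a2 and Gars stayed higher (corrected log2 fold changes 1.48, 0.98, 0.92 and 1.70, edgeR adjusted p = 0.0023, 0.026, 0.016 and 0.019). The list passed camera in all 5 corrections at the preset correlation. The 3 by transcript length, however, left part of the coding length trend (Spearman's rho 0.26 to 0.32). With the correction and an estimated correlation the list did not pass (camera adjusted p = 0.24). With coding length alone corrected only Nars of these 4 genes passed (edgeR adjusted p = 0.0019, against 0.36 for Asns, 0.107 for Slc3a2 and 0.175 for Gars).

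Other groups passed camera as fitted and did not with the length correction. With an estimated correlation they did not pass either (adjusted p = 0.33, 0.27 and 0.33 for the unfolded protein response, anaplerosis and lysosome lists). Of 28 genes of the unfolded protein response, which answers a load of unfolded protein in the endoplasmic reticulum, 17 rose and 4 fell (18 and 4 adjusted over the list alone), with a median of 1.31 that turned to -0.51 when corrected (6 higher and 9 lower), or -0.20 relative to the all-gene median. Hsp90b1, the chaperone GRP94, rose from 95.1 ± 35.6 to 1294 ± 176 CPM and stayed higher when corrected (log2 1.89, edgeR adjusted p = 0.0015). Canx, Sel1l and Atf6b rose by log2 2.79, 2.30 and 3.26 as fitted and did not pass when corrected. Of 23 anaplerosis and glutamine genes 12 rose and 0 fell (13 and 0 adjusted over the list alone), with a median of 1.87 that was 0.01 when corrected (2 higher and 3 lower), or 0.32 relative to the all-gene median. Among them Got2, mitochondrial aspartate aminotransferase, rose by log2 3.19 and Slc38a2, a glutamine transporter, by log2 2.62, and neither passed when corrected (edgeR adjusted p = 0.059 and 0.076). Glud1, glutamate dehydrogenase, rose by log2 3.43 and was 0.88 when corrected (adjusted p = 0.51). Slc25a22, a mitochondrial glutamate carrier, rose by log2 6.74 from 5 control counts in all and passed when corrected (log2 5.41, adjusted p = 0.028). Of 32 lysosome and autophagy genes 11 rose and 2 fell (11 and 2 adjusted over the list alone), with a median of 1.27 that turned to -0.15 when corrected (3 higher and 5 lower), or 0.16 relative to the all-gene median. Ctsz and Sqstm1 rose by log2 2.46 and 2.51 and stayed higher when corrected (log2 1.83 and 0.91, edgeR adjusted p = 0.00099 and 0.040), and Gabarapl2 fell by 2.18 on the log2 scale. The camera adjusted p of these 3 lists was 0.000323, 0.00399 and 0.0408. The lysosome list lost its call with upper-quartile factors (adjusted p = 0.095) and without control replicate 2, 3 or 4 (adjusted p = 0.095, 0.090 and 0.065).

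The respiratory chain, ribosomal protein and proteasome lists were lower as fitted and lost their calls with an estimated correlation. Of 80 nuclear-encoded respiratory chain genes 2 rose and 65 fell (4 and 69 adjusted over the list alone), with a median of -1.96. Cox7c, a subunit of cytochrome oxidase, fell from 1025 ± 139 to 129 ± 16.9 CPM (SD, n = 4 and 3). Atp5k, Ndufs5 and Ndufb5 fell by 2.75, 2.56 and 2.16 on the log2 scale. Of 82 cytosolic ribosomal protein genes 1 rose and 72 fell (1 and 73 adjusted over the list alone), with a median of -2.07, among them Rps27, from 3130 ± 584 to 541 ± 53.1 CPM, and Rpl22l1, Rpl27a and Rpl35a, which fell by 2.99, 2.14 and 2.58 on the log2 scale. When corrected Cox7c, Ndufs5, Ndufb5 and Rpl27a stayed lower (log2 -0.53, -0.71, -1.17 and -0.95), against an all-gene median of -0.31. Atp5k (log2 -0.42, edgeR adjusted p = 0.073), Rps27 (0.16, 0.40), Rpl22l1 (-0.16, 0.62) and Rpl35a (-0.25, 0.27) did not pass when corrected. Ribosomal protein genes have many processed pseudogenes, so their counts are uncertain where reads were shared. Median coding lengths of these 2 lists were 426 and 453 bases. Corrected medians were -0.58 and -0.37, or -0.27 and -0.06 relative to the all-gene median, with 3 higher and 44 lower of 80 respiratory chain genes and 5 higher and 31 lower of 81 ribosomal protein genes. Both lists passed camera at the preset correlation when corrected (adjusted p = 1.30e-08 and 5.04e-05) and with coding length alone corrected (5.95e-15 and 1.00e-18), and did not with the correction and an estimated one (0.24 and 0.82). As fitted camera gave adjusted p = 3.74e-38 and 7.83e-45, and 0.17 and 0.27 with an estimated correlation. Of 37 proteasome genes 6 rose and 21 fell (8 and 21 adjusted over the list alone), with a median of -0.93 and a corrected median of -0.67, or -0.35 relative to the all-gene median (camera adjusted p = 0.000323, and 0.33 with an estimated correlation; when corrected 3 higher and 18 lower, adjusted p = 4.76e-06, and 0.24 with an estimated correlation). Psma2, Psma3, Psmb1 and Psmb4 fell by 1.79, 2.37, 2.07 and 1.87 on the log2 scale, and all 4 stayed lower when corrected, by 1.18, 2.07, 1.66 and 1.69. The proteasome list lost its call in the 3 corrections by transcript length (camera adjusted p = 0.104, 0.065 and 0.176).

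Of 12 respiratory chain genes on the mitochondrial genome 0 rose and 5 fell, the same counts when adjusted over the list alone, with a median of -1.11. Its direction depended on the correction: the median was 0.02 when corrected, -1.38 with coding length alone (camera adjusted p = 0.0040), and -0.31, 1.13 and 1.38 in the 3 corrections by transcript length. The 4 with the smallest p, mt-Nd2, mt-Co2, mt-Nd3 and mt-Co3, fell by 2.11, 1.97, 2.51 and 1.13 on the log2 scale as fitted, and none of the 4 passed when corrected. Camera called the list (adjusted p = 0.00761), while an estimated correlation did not (adjusted p = 0.56) and fry did not (adjusted p = 0.062). Mitochondrially encoded genes made up 0.188 ± 0.062% of counts in the deleted-labelled libraries and 0.347 ± 0.123% in the controls (SD, n = 3 and 4; exact permutation p = 0.171).

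Other metabolic lists did not pass camera as fitted. Of 23 glycolysis genes 10 rose and 0 fell (10 and 0 adjusted over the list alone; camera adjusted p = 0.0509), with a median of 0.92 that turned to -0.63 when corrected (1 higher and 4 lower). The list passed with immunoglobulin genes removed, with no low-count filter, without control replicate 3 and without each deleted-labelled library (camera adjusted p from 0.0093 to 0.0475), and did not with an estimated correlation (0.29). Gapdh rose from 179 ± 45.1 to 579 ± 32.6 CPM and stayed higher when corrected (log2 1.36, edgeR adjusted p = 0.0051), while Eno1, Pkm and Pfkl, higher by log2 1.62, 1.79 and 4.28 as fitted, did not pass when corrected. Of 31 genes of the TCA cycle and pyruvate entry 8 rose and 4 fell (9 and 5 adjusted over the list alone; adjusted p = 0.456), and when corrected 1 was higher and 4 lower, and the median went from 0.81 to -0.35. Mpc2, part of the mitochondrial pyruvate carrier, fell from 678 ± 160 to 94.4 ± 11.0 CPM and stayed lower when corrected (log2 -1.76, edgeR adjusted p = 0.00085), and Ogdh and Sdha rose by log2 3.79 and 3.13 and did not pass when corrected. Of 28 pentose phosphate and nucleotide synthesis genes 7 rose and 3 fell (9 and 4 adjusted over the list alone; adjusted p = 0.383; when corrected 1 higher and 6 lower, and the median went from 0.90 to -0.39). Impdh1 and Cad were higher by log2 2.55 and 6.27 and Prps1 lower at -1.42, of which Impdh1 did not pass when corrected (log2 0.11, edgeR adjusted p = 0.86). Of 27 fatty acid oxidation genes 4 rose and 3 fell (4 and 2 adjusted over the list alone; adjusted p = 0.637; when corrected 0 higher and 5 lower, and the median went from 0.68 to -0.51). Acsl5 and Hadha were higher by log2 2.22 and 2.73 and Etfb was at -1.03, none of which passed when corrected (log2 -0.72, -0.53 and -0.42, edgeR adjusted p = 0.40, 0.67 and 0.18). Of 27 sterol and fatty acid synthesis genes 9 rose and 2 fell (10 and 2 adjusted over the list alone; adjusted p = 0.0788, and 0.0131 with no low-count filter, and 0.33 with an estimated correlation; when corrected 2 higher and 2 lower, and the median went from 2.01 to 0.19). Among them Fasn and Scd2 were at log2 3.87 and 3.58 and Ebp at -1.04, of which Fasn did not pass when corrected (log2 1.22, edgeR adjusted p = 0.22). Scd2 passed when corrected, but not in the 3 corrections by transcript length (edgeR adjusted p = 0.051, 0.055 and 0.095). Of 37 hexosamine and N-glycosylation genes 13 rose and 6 fell (13 and 6 adjusted over the list alone; adjusted p = 0.31; when corrected 2 higher and 10 lower with a median of -0.73, camera adjusted p = 0.0484, direction down, and 0.84 with an estimated correlation). Fut8, Stt3b and Rpn2 were at log2 3.27, 2.39 and 3.37 and Ostc at -2.01. Of these only Fut8 passed when corrected (log2 1.54, edgeR adjusted p = 0.0075), and Stt3b, Rpn2 and Ostc were at -0.68, 0.75 and -0.48. None of the 5 tested glucose transporters passed (camera adjusted p = 0.521, with 0 and 0 adjusted over the list alone). Nor did any of 3 genes listed for the glucose sensor MondoA (0 and 0 adjusted over the list alone). Its targets Txnip and Arrdc3 were at log2 -0.07 and 0.92, and Mlxip, which encodes MondoA itself, was at 1.87. When corrected Txnip passed as lower (log2 -1.47, edgeR adjusted p = 0.020), and Arrdc3 and Mlxip did not pass.

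Secretory, growth and stress lists were mixed. Of 40 genes of secretory translocation and transport 15 rose and 17 fell (16 and 17 adjusted over the list alone; camera adjusted p = 0.618, direction down, with a median of 0.22 and a mean of 0.83; when corrected 7 higher and 13 lower). Lman1, a cargo receptor for export from the endoplasmic reticulum, rose from 26.5 ± 10.6 to 308 ± 28.04 CPM and stayed higher when corrected (log2 2.63, edgeR adjusted p = 0.00044). Sec24c rose by log2 3.02, and Sec61b and Sec11c fell by 2.54 and 2.35 on the log2 scale. When corrected Sec61b and Sec11c stayed lower (log2 -0.63 and -1.12, against an all-gene median of -0.31) and Sec24c did not pass (log2 -0.085, edgeR adjusted p = 0.87). Of 23 oxidative stress genes 3 rose and 9 fell (5 and 9 adjusted over the list alone; camera adjusted p = 0.0509, direction down, with a median of 0.09 and a mean of 0.34). Gpx1, Gpx4, Prdx1 and Txn1 fell by 2.34, 2.01, 2.09 and 2.02 on the log2 scale, and all but Txn1 stayed lower when corrected (log2 -2.05, -1.63 and -1.43). The oxidative stress list passed camera in 5 of the planned settings and passed fry, but not with an estimated correlation (adjusted p = 0.33) or when corrected (0.20, with 2 higher and 6 lower). Of 34 mTORC1 and Myc genes 8 rose and 5 fell (11 and 6 adjusted over the list alone; adjusted p = 0.383; when corrected 2 and 6), and of 16 hypoxia genes 3 rose and 2 fell (4 and 2 adjusted over the list alone; adjusted p = 0.848; when corrected 1 and 3). Of 39 cell cycle genes 5 rose and 6 fell (5 and 6 adjusted over the list alone; adjusted p = 0.848, direction down, with a median of 0.50 and a mean of 0.84; when corrected 0 higher and 6 lower). The 4 with the smallest p were lower, Cdk1 from 86.4 ± 32.8 to 16.8 ± 2.68 CPM and Pcna, Tyms and Cenpa by log2 values of -1.73, -1.63 and -2.18, and all 4 stayed lower when corrected. With coding length alone corrected, Cenpa did not pass (log2 -0.93, edgeR adjusted p = 0.059). Of 28 survival and death genes 2 rose and 5 fell (1 and 4 adjusted over the list alone; adjusted p = 0.652, direction down, with a median of 0.44 and a mean of 0.33; when corrected 1 higher and 4 lower). Tnfrsf13c, the BAFF receptor, was higher at log2 2.10 and Cflar, an inhibitor of caspase 8, lower at -1.45. Of 24 interferon-stimulated genes 6 rose and 4 fell (6 and 4 adjusted over the list alone; adjusted p = 0.646; when corrected 2 and 3), and of 21 immediate early genes 3 rose and 1 fell (0 and 0 adjusted over the list alone; adjusted p = 0.652, direction down, with a median of -0.25 and a mean of 0.07). The immediate early list passed when corrected (median -1.18, 0 higher and 4 lower, camera adjusted p = 0.0484), and not with an estimated correlation (0.82).

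Lists of plasma cell and B cell identity genes held large differences in single genes and did not pass as lists in the fit without correction. Of 33 plasma cell genes 11 rose and 2 fell (11 and 2 adjusted over the list alone; camera adjusted p = 0.0562). With the correction the list passed (camera adjusted p = 0.0295, direction up, 10 members higher and 3 lower), and with an estimated correlation it did not (0.75); the other 4 corrections did not call it. Both identity lists passed with immunoglobulin genes removed, with no low-count filter and without some of the deleted-labelled libraries, and neither passed with an estimated correlation (adjusted p = 0.29 for plasma cell and 0.51 for B cell genes). Irf4, a transcription factor required by plasma cells, rose from 18.9 ± 5.45 to 113 ± 10.3 CPM but did not pass when corrected (log2 0.81, edgeR adjusted p = 0.10). Tnfrsf13b, which encodes the sorting marker TACI, rose by log2 1.58 (corrected 1.76, but not past the threshold in the 3 corrections by transcript length), and Mzb1, a chaperone of immunoglobulin assembly, fell from 23444 ± 4538 to 5683 ± 1019 CPM (corrected log2 -1.22, adjusted p = 0.00095). Of 33 B cell genes 10 rose and 2 fell (11 and 2 adjusted over the list alone; camera adjusted p = 0.0509), and 6 were higher and 2 lower when corrected. Cd74, the invariant chain of MHC class II (chromosome 18, 60803848 to 60812652), rose 17.1-fold from 261 ± 144 to 4466 ± 808 CPM and stayed higher when corrected (log2 3.67, edgeR adjusted p = 0.0012). Fcer2a, which encodes CD23, rose from 0.131 ± 0.0797 to 11.7 ± 6.13 CPM, and Blnk, a B cell receptor adaptor, by log2 3.47, and both stayed higher when corrected (log2 5.49 and 2.05). Of 25 homing and adhesion genes 8 rose and 2 fell (9 and 3 adjusted over the list alone; camera adjusted p = 0.0509). Selplg and Itgal were at log2 2.84 and 4.04 and Cd9 at -2.52, of which Itgal did not pass when corrected (log2 0.83, edgeR adjusted p = 0.099). The homing list passed with immunoglobulin genes removed, with no low-count filter, with the replicate block, without control replicate 1 and without each deleted-labelled library (camera adjusted p from 0.0127 to 0.0475), and did not with an estimated correlation (0.28). When corrected 2 members were higher and 5 lower, and the median went from 1.53 to -0.29.

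Markers of cells that a CD138 and TACI gate could still hold were also compared. Of 11 erythroid and platelet markers 0 rose and 5 fell, the same counts adjusted over the list alone, with a median of -2.84 (camera adjusted p = 0.00625, and 0.33 with an estimated correlation; 0.054 without control replicate 4). When corrected the list lost its call, with a median of -1.63 and 3 members lower (camera adjusted p = 0.148, and 0.091 with coding length alone corrected). Hbb-bs was at 1295 ± 780 CPM in the controls and 185 ± 89.0 CPM in the deleted-labelled libraries, and Hba-a2 at 840 ± 384 and 111 ± 27.8 CPM (SD, n = 4 and 3). Hba-a2 passed when corrected (edgeR adjusted p = 0.020) and Hbb-bs did not (0.096). Reads of the near-identical Hba and Hbb copies can be shared, so their split is uncertain. Of 12 T and NK cell markers 0 rose and 2 fell (0 and 2 adjusted over the list alone; adjusted p = 0.346; when corrected 0 higher and 1 lower of 9). These were Cd3d at log2 -3.15 and Gzma at -3.41, of which Gzma did not pass when corrected (edgeR adjusted p = 0.23). Of 13 myeloid markers 2 rose and 2 fell (2 and 2 adjusted over the list alone; adjusted p = 0.848; when corrected 2 higher and 0 lower). S100a8 and S100a9 were lower at log2 -4.65 and -4.59 and did not pass when corrected (edgeR adjusted p = 0.27 and 0.26), Cd68 was higher at 2.71, and Itgam, which encodes CD11b, had no control count and 7.22 ± 1.95 CPM in the deleted-labelled libraries, at least 264-fold higher with a floor of 3 counts over the control group. Of 9 dendritic cell markers 3 rose and 1 fell (5 and 1 adjusted over the list alone; adjusted p = 0.346; when corrected 2 higher and 1 lower). Ccr9 and Tcf4 were among those higher, of which Tcf4 did not pass when corrected (edgeR adjusted p = 0.20). Neither of 2 stromal markers passed as fitted (0 and 0 adjusted over the list alone), and 1 was lower when corrected. Of 4 tested sex-linked genes, all on the Y chromosome, Ddx3y was higher at log2 2.29 (1 and 0 adjusted over the list alone) and did not pass when corrected (edgeR adjusted p = 0.63). In deleted-labelled replicate 1 some of the other Y-linked genes were at 0 CPM and Ddx3y at 14.4 CPM. Those genes were above 0 CPM in every other library, and the reason was not tested.

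Among single genes ranked by size of change, many of the higher ones were near 0 in the controls. Srp54a had no control count and 38.4 ± 12.2 CPM in the deleted-labelled libraries, at least 1408-fold higher with the same floor, but near-identical Srp54 copies make its count uncertain. Cables2 had no control count either and was at least 343-fold higher. Lss, which makes lanosterol, had 1 control count and 13.6 ± 7.87 CPM in the deleted-labelled libraries, a pooled ratio of 1545 with a 95% counting interval of 277 to 61012. Prep, Trappc9, Ccr9 and Repin1 had 1 control count each, with pooled ratios of 1413, 1291, 1113 and 1046. R3hcc1, Tdp1, Abcf2, Dpp8, Acap3, Casc3 and Ltv1 made up the rest of the higher set with Ighg3. The lower set held histone genes, with Hist1h1d from 38.2 ± 3.28 to 3.005 ± 0.258 CPM (edgeR adjusted p = 0.000284, corrected log2 -2.83) and Hist4h4 and Hist1h1a at log2 -4.52 and -4.33, of which Hist1h1a did not pass when corrected (edgeR adjusted p = 0.055). It also held Rn7s2, a 7SL gene, from 16215 ± 3134 to 1494 ± 360 CPM, Hbb-bt, S100a8 and S100a9, the pseudogenes Rps2-ps6 and Rps2-ps10, a pair of ACEA_U3 small RNA genes, Pydc4, Sag, Lrr1 and Fam221b. Of the protein-coding ones Pydc4, S100a8 and S100a9 did not pass when corrected. Counts of these pseudogenes and small RNA copies are uncertain for the same reason.

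Immunoglobulin transcripts took a larger share of counts in the deleted-labelled libraries, and the heavy chain constant genes differed in their proportions, but no share passed adjustment over 12 measures. Immunoglobulin genes made up 41.1 ± 1.46% of all counts in the deleted-labelled libraries (SD, n = 3) and 14.5 ± 0.536% in the controls (SD, n = 4; exact permutation p = 0.0286, adjusted 0.0686). Ighm, the constant gene of IgM, was 40.3 ± 5.26% against 72.4 ± 5.68% of heavy chain constant counts, Igha, of IgA, 32.8 ± 10.6% against 14.9 ± 4.05%, and Ighg3, of IgG3, 9.65 ± 2.73% against 1.44 ± 1.84%. Lambda constant genes were 12.3 ± 6.13% against 27.1 ± 4.91% of light chain constant counts. The groups did not overlap in these 5 measures, each with exact p = 0.0286 and adjusted 0.0686, two-sided. With 35 assignments the smallest possible p is 0.0286, and 2.86% of splits reach it by construction for each measure. With 5 of 12 measures at that smallest p, their adjusted value cannot fall below 0.0686. Missing the threshold here therefore reflects the number of assignments and measures, and does not show that the shares were alike. Ighg2c (9.68 ± 5.97% against 4.33 ± 1.78%), Ighg2b (6.59 ± 2.45% against 4.02 ± 1.70%), Ighg1 (1.02 ± 0.900% against 2.82 ± 3.49%), Ighd and Ighe gave exact p from 0.0857 to 1. Ighg2b and Ighg2c are close in sequence, so their split is uncertain. The most abundant heavy chain V gene held 14.3 ± 7.49% of heavy V counts in the deleted-labelled libraries and 18.2 ± 4.44% in the controls (exact p = 0.371).

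**Figure D3:**
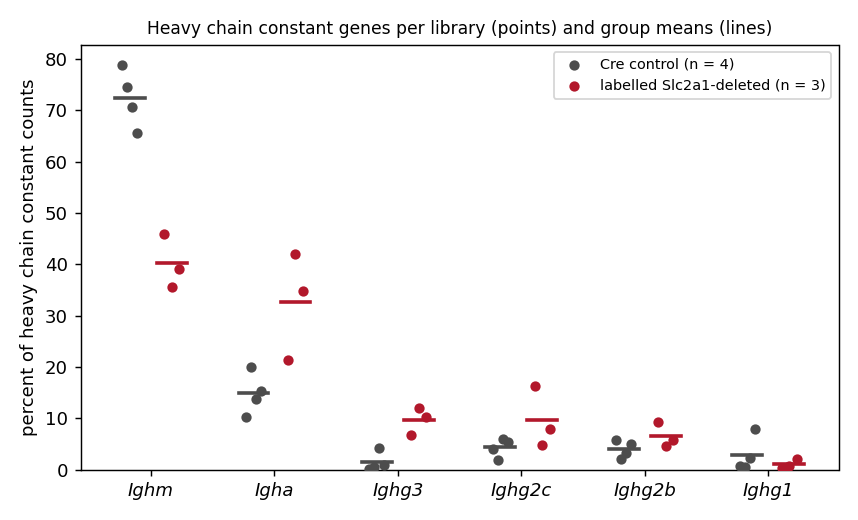
Percent of heavy chain constant counts on each of 6 constant genes, with a point per library and a line at each group mean. Ighm is lower and Igha and Ighg3 are higher in the 3 deleted-labelled libraries than in any of the 4 controls.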

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

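The 4 control libraries were compared with each other for 138 reported values, and 16 had 1 library far from the other 3. Chance alone flags about 1 in 20 groups, but 5 of the 16 are a single count against 0 in the other 3, which meets the criterion by construction, so that rate says nothing about those 5. By library, 8 of the 16 were in control replicate 2, 3 in replicate 1, 4 in replicate 3 and 1 in replicate 4. In control replicate 2 the globin genes stood apart, with Hbb-bs at 2466 CPM against 880 to 927 CPM in the others and Hbb-bt at 1528 CPM against 320 to 477 CPM. The same library had Sag at 13.1 CPM against 4.77 to 6.16 CPM, Hist1h1a at 8.78 CPM against 7.18 to 7.41 CPM, Abcf2 at 0.219 CPM against 0 to 0.037 CPM, and Ighe at 0.0178% of heavy chain constant counts against at most 0.00046%. Control replicate 1 had Slc2a3 at 5.17 CPM against 0 to 0.073 CPM and Itgal at 23.1 CPM against 7.54 to 9.84 CPM. Control replicate 3 had Pcna at 211 CPM against 123 to 137 CPM, and Ighg3 at 4.17% of heavy chain constant counts against 0.195% to 0.844%. Control replicate 4 had Glud1 at 7.51 CPM against 1.11 to 2.01 CPM. The remaining 5 values were each a single count in 1 control and 0 in the other 3: Lss and Trappc9 at 0.0366 CPM in replicate 2, Prep at 0.0367 CPM in replicate 1, and Ccr9 and Repin1 at 0.0318 CPM in replicate 3. No explanation was tested for these values. The genes compared here are the 119 named in the text; over all 154 table IDs of the genes the naming rule took, 17 had 1 control far from the others, shares and library measures not included.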

How the results depend on the processing

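The 5 length corrections, and the run on protein-coding genes alone, were chosen after the data were seen; the other settings were chosen before the data were examined. The counts of 1825 genes higher and 1595 lower stayed within 1.5 times under most planned settings. For genes higher, limma-voom gave 3684 and its weighted form 3655, and leaving out 1 library gave 941 to 1749. The corrections gave 579 (coding length), 496 (with untranslated length and GC), 777 (transcript length), 699 (then GC) and 700 (iterated). For genes lower, leaving out 1 library gave 1128 to 1976. With the correction for coding length, untranslated length and GC, 1191 of the genes called were also called without it, 1142 of these in the same direction. Slc2a1 kept its direction and missed the threshold in every planned setting, at log2 0.34 to 0.98 with adjusted p from 0.0715 to 0.493. It turned with each correction, to -0.94, -1.62, -0.97, -1.30 and -1.39 in the same order, with edgeR adjusted p = 0.127, 0.0227, 0.119, 0.052 and 0.041, so 2 of 5 passed. Camera called 9 lists; an estimated correlation called 0 (5 at an unadjusted p under 0.05), fry 23, removal of immunoglobulin genes 14, no low-count filter 15, leaving out 1 library 7 to 14, and the corrections 5, 7, 3, 5 and 5 in the same order. No immunoglobulin share passed adjustment; leaving out a library or pairing leaves too few assignments for any share to pass, so these settings say nothing on stability. The cause of these differences was not tested.

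The replicate number as a block gave 1647 genes higher, 1335 lower, 10 lists and Slc2a1 at log2 0.92. Deviations of same-numbered samples correlated at 0.029, 0.048 and 0.023, so the numbers were not taken to pair the samples, although each deleted-labelled sample correlated best with its own number, a hint from the data and not the design. The sex covariate was not run, since Xist had no count. Of 2116 comparisons of 119 named genes with planned settings, 2063 kept direction and side of the threshold, 36 lost and 11 gained a call and 6 turned; of 696 with added settings, 533 kept both, 110 lost and 5 gained a call and 48 turned. These 119 were chosen from the 153 genes of the naming rule after the values and their stability had been seen, and the choice favours stable genes: over all 153, 2588 of 2721 planned comparisons kept both, 100 lost and 13 gained a call and 20 turned, and of 897 added ones 651 kept both, 150 lost and 10 gained a call and 86 turned. For the 34 left out alone, 525 of 605 planned comparisons kept both. The corrected values in the text come from 1 of the 5 corrections, the one with the most lists called and the smallest adjusted p for Slc2a1. Of 67 named genes called as fitted and with it, 60 were also called in the other 4. The 3 corrections by transcript length left Spearman's rho between fold change and coding length at 0.29, 0.32 and 0.26, against 0.59 as fitted. The coding length corrections left it at -0.08 and -0.09. The 3 forms of transcript length thus removed only part of the coding length trend. Asns, Slc3a2, Gars and Cenpa lost the call with coding length alone, Lrr1 with the iterated form, and Scd2 and Tnfrsf13b in all 3 forms of transcript length. DESeq2 gave no adjusted p for 147 genes, which stay out of these counts.

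Turned log2 fold changes with upper-quartile factors were Slc2a8 -0.12 alone. In the setting with upper-quartile factors, list medians changed sign for secretory translocation and transport -0.18, oxidative stress response -0.30 and myeloid cell markers -0.34. With limma-voom with quality weights, log2 fold changes turned for Txnip 0.036. Turned log2 fold changes with the replicate block were Txnip 0.17. In the setting with the replicate block, list medians changed sign for myeloid cell markers -0.15. With RLE factors, list medians turned for oxidative stress response -0.036 and myeloid cell markers -0.075. Turned list medians with no low-count filter were immediate early and handling stress 0.62 and T and NK cell markers 0.15. Leaving out 1 library gave ranges that cross 0 for Slc2a8 (-0.24 to 0.55), Txnip (-0.39 to 0.075), secretory translocation and transport (-0.12 to 0.27), HIF1 and hypoxia (-0.43 to 0.96), oxidative stress response (-0.25 to 0.13), myeloid cell markers (-0.63 to 1.71) and Ighe share (-0.0028 to 0.0036), the last in percentage points.

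Turned log2 fold changes with coding length offsets were Slc2a8 -1.50, Slc2a6 -0.029, Slc45a4 -1.31, Pkm -0.20, Acsl5 -0.44, Hadha -0.080, Stt3b -0.37, Sel1l -0.45, Arrdc3 -0.32, Mlxip -0.73 and Ddx3y -0.24. In the setting with coding length offsets, list medians changed sign for glucose transporters -0.94, glycolysis -0.44, pentose phosphate and nucleotide synthesis -0.67, TCA cycle and pyruvate entry -0.36, fatty acid oxidation -0.70, hexosamine pathway and N-glycosylation -0.72, unfolded protein response -0.16, secretory translocation and transport -0.091, HIF1 and hypoxia -0.30, oxidative stress response -0.47, cell cycle -0.67 and homing and adhesion -0.019. With offsets for coding length, untranslated length and GC, log2 fold changes turned for Slc2a8 -1.84, Slc2a6 -0.38, Slc45a4 -1.92, Eno1 -0.12, Pkm -0.63, mt-Nd3 0.85, mt-Co3 0.080, Acsl5 -0.72, Hadha -0.53, Stt3b -0.68, Sel1l -0.67 and Sec24c -0.085. Further ones were Arrdc3 -0.011, Mlxip -1.29 and Rps27 0.16. Turned list medians with offsets for coding length, untranslated length and GC were glucose transporters -1.62, glycolysis -0.63, pentose phosphate and nucleotide synthesis -0.39, TCA cycle and pyruvate entry -0.35, mitochondrially encoded respiratory chain 0.022, fatty acid oxidation -0.51, hexosamine pathway and N-glycosylation -0.73, unfolded protein response -0.51, secretory translocation and transport -0.096, HIF1 and hypoxia -0.40, oxidative stress response -0.40 and lysosome and autophagy -0.15. Further ones were cell cycle -0.50 and homing and adhesion -0.29. In the setting with transcript length offsets, log2 fold changes changed sign for Slc2a8 -0.58, Slc45a4 -0.15, mt-Co3 0.19, Etfb 0.19 and Arrdc3 -1.18. With transcript length offsets, list medians turned for glucose transporters -0.15, pentose phosphate and nucleotide synthesis -0.32, TCA cycle and pyruvate entry -0.034, hexosamine pathway and N-glycosylation -0.52, secretory translocation and transport -0.36, HIF1 and hypoxia -1.03, oxidative stress response -0.73, cell cycle -0.41 and survival and death regulators -0.80. Turned log2 fold changes with offsets for transcript length and then GC were Slc2a8 -1.31, Slc45a4 -0.38, Pkm -0.062, mt-Nd2 0.49, mt-Co2 0.51, mt-Nd3 0.36, mt-Co3 1.36 and Arrdc3 -0.25. In the setting with offsets for transcript length and then GC, list medians changed sign for glucose transporters -0.38, glycolysis -0.062, pentose phosphate and nucleotide synthesis -0.035, TCA cycle and pyruvate entry -0.027, mitochondrially encoded respiratory chain 1.13, hexosamine pathway and N-glycosylation -0.48, secretory translocation and transport -0.18, HIF1 and hypoxia -1.0, oxidative stress response -0.62, cell cycle -0.51 and survival and death regulators -0.59. With iterated offsets for transcript length and GC, log2 fold changes turned for Slc2a8 -1.29, Slc45a4 -0.70, Pkm -0.072, mt-Nd2 0.76, mt-Co2 0.76, mt-Nd3 0.53, mt-Co3 1.61, Arrdc3 -0.30 and Mlxip -0.29. Turned list medians with iterated offsets for transcript length and GC were glucose transporters -0.70, glycolysis -0.072, mitochondrially encoded respiratory chain 1.38, hexosamine pathway and N-glycosylation -0.47, secretory translocation and transport -0.14, HIF1 and hypoxia -0.97, oxidative stress response -0.61, cell cycle -0.49 and survival and death regulators -0.42. In the setting with protein-coding genes alone, list medians changed sign for oxidative stress response -0.020 and myeloid cell markers -0.044. The all-gene median moved from 0.62 to between -0.31 and -0.27 with the corrections, so part of these turns is that shift. Depth limits the genes with few control counts, whose fitted folds depend on the prior count.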

Other observations

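All tests in this part were chosen after the results they bear on had been seen, at least in part, except the counts over other splits of the samples. Some heavy and kappa V genes that B-1 cells, an innate-like B cell population, are known to use were more abundant in the deleted-labelled libraries. Ighv11-2 made up 3.37 ± 1.14% of heavy V counts (SD, n = 3) against 0.619 ± 0.377% in the controls (SD, n = 4), and Igkv14-126 2.18 ± 0.712% against 0.682 ± 0.261% of kappa V counts, with no overlap for either gene (exact permutation p = 0.0286 each, unadjusted). The other 2 genes of the set did not follow, with Ighv12-3 at 0.0592 ± 0.0079% against 0.208 ± 0.134% and Igkv4-91 at 0.403 ± 0.021% against 0.495 ± 0.429% (exact p = 0.171 and 1). A larger share of plasma cells of B-1 origin is a hypothesis that could be raised from Ighv11-2. Ighv11-2 and Ighv12-3 together made up 3.43% of heavy V counts in the deleted-labelled libraries against 0.827% in the controls, but the kappa pair overlapped between groups (2.58 ± 0.729% against 1.18 ± 0.648%, exact p = 0.0857). The question stays open.

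The calls followed coding length. Among genes in none of the fixed lists Spearman's rho of fold change on coding length was 0.57, but coding length had been picked for its rho over mostly the same genes, so this restates the pattern. A length-dependent yield that differs between the groups therefore cannot be told apart from a difference by genotype, since the slopes per library line up with the labels. Lower respiratory chain and ribosomal protein transcripts apart from length cannot be told apart from that yield: their corrected medians were -0.58 and -0.37, or -0.27 and -0.06 relative to the all-gene median, a reading added after the values were seen, although both lists passed camera at the preset correlation when corrected (adjusted p = 1.30e-08 and 5.04e-05) and not with an estimated one (0.24 and 0.82). Of the 35 splits of the 7 libraries 1, the real one, gave as many as 3420 genes, and the highest other gave 0. The real split alone is 2.86% of splits, the smallest share possible with 35, so chance is not excluded for that number. Every other split puts libraries of both labels in the same group, so its 0 calls are a weak measure of chance. The number also says nothing about genotype against library composition. For the lists, 5 of the 35 splits gave 9 or more, the highest other 11, so chance cannot be excluded for the number of lists. Of the 4 others, 3 set 3 controls against the rest and so keep much of the real contrast.

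Slc2a1 was not lower in the deleted-labelled libraries. Libraries correlated better with their own group in 7 of 7 cases, but library composition lines up with the labels and can drive this, so a swap of genotypes before the libraries were made stays open. A length-dependent yield that differs between the groups may hide a decrease: Slc2a1 was lower in all 5 length corrections, but past the threshold in 2 of them, so the length-dependent yield and an unchanged Slc2a1 cannot be told apart here. Whether reads fall in the floxed exons was not examined, as the table has no exon counts.

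The switched isotypes Igha and Ighg3 were higher among heavy chain constant counts, without passing adjustment over 12 measures. The coding length trend of other genes predicts a log2 change of -0.49 in the ratio of Igha to Ighm. The observed change was 1.98 with a pooled SD of 0.56. However, Ighg3 (1196 coding bases) changed by log2 7.36, against a median of 0.88 for protein-coding genes of 1000 to 1500 coding bases. That fold change is of its level among all counts, so it also holds any change of heavy chain constant counts as a whole. Immunoglobulin genes went from 14.5% to 41.1% of all counts. The share of Ighg3 among heavy chain constant counts went from 1.44% to 9.65%, so 7.36 is not a measure of isotype alone. The trend of other genes may thus not hold for heavy chain constant genes, and the prediction does not settle whether yield contributes. The heavy chain shares rest on as few as 79825 counts in a library. The share of the most abundant heavy V gene exceeded the highest control in 0 of the 3 deleted-labelled libraries. A V gene share does not measure clones, since dominant clones can use different V genes, so a few dominant clones were not excluded. A difference in isotype with genotype is a hypothesis that these tests leave open; cells of another origin in the gate, such as the B-1 lineage above, were not excluded.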
